A study of Mus musculus with 10 samples.

How the data were processed

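Total RNA of mouse pancreas was measured in 10 samples, 5 control and 5 DKO, of mixed strain background. Per the labels' protocols, RNA was isolated with RNeasy columns, and total RNA was converted to cDNA, amplified, labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays. Per the submitters' processing notes, array data were processed with Affymetrix Expression Console. Its version, and the methods of background correction, summarization and normalization, are not given in the sources used here. The values deposited by the authors are log2 levels, 1 per transcript cluster and sample, which by their range (2.79 to 13.94) are log2 intensities. Array medians over all clusters agree to within a few hundredths (7.12 to 7.15), so the deposited log2 values had already been brought to a common scale, and genes had not been centred. They were used as deposited, with no further normalization, filter or pseudocount.

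The table held 35556 clusters. By the platform annotation 21789 had 1 gene symbol, 1621 had several and 12146 had no gene name here, a class that includes control clusters. Only clusters with 1 symbol entered the tests, and for the 999 genes with more than 1 cluster, the cluster with the highest mean over all 10 arrays stood for the gene, which left 19938 genes. Gene identifiers of 21698 of the 21789 clusters were found in a RefSeq gene table of assembly GRCm38.p6, which served to update symbols and to find which genes neighbour each other. No genome build is named by the authors' labels, so no coordinates are given. The control genotype beyond the word control is not given in the labels.

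Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust settings, a moderated two-sided test), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Unless another test is named, adjusted p-values of single genes are from this limma fit. Errors of log2 changes of single genes are standard errors from the fit with 10.96 total degrees of freedom, and errors of group means are SDs over 5 arrays. Errors of differences in list means are standard errors from the variances of the per-array means within each group. Of 692 genes placed in lists before the data were examined, 637 were measured, and 24 genes belong to more than 1 list. The 30 lists tested covered the Hippo pathway and YAP and TAZ targets, exocrine, duct, endocrine and progenitor cells, injury, matrix, immune, vascular, muscle, fat, gut and blood cells, and stress, cell cycle and metabolic pathways. Another list of sex-linked genes was described per array and not tested. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Beside it, the mean of a list per array was compared by an exact two-sided permutation test over all 252 splits, also adjusted over the lists. The number of members past the threshold was counted over all genes and again adjusted over the list alone.

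The genes named in the text were chosen by a rule set in advance: both deleted kinases; the 12 largest increases and 12 largest decreases past the threshold in which all 5 DKO arrays lay on the same side of the control mean, without predicted loci; up to 4 members of each list with the smallest p; and the sex-linked genes. Other names are of list members or neighbours chosen after their values were seen, including Ptpn14, Anxa10, Yap1, Wwtr1, Ccn2, Sox9 and Cftr as duct genes, Ctrc, Slc35c2, the hepatocyte genes and the further genes of the closing section. Members of near-identical families (elastases, trypsins, amylases and the Clca3 pair) may share probes, so single values of these genes are uncertain.

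The fit was tested on simulated data with the mean and spread of the 19938 genes in the comparison of DKO against control. It recovered 71.6% of 67 genes changed by 0.5 on the log2 scale, 100% of 67 changed by 1 and 100% of 66 changed by 2, with 12 false calls beside them and 0 when no gene was changed. With independent genes, 0 of 30 lists were called when none was changed, and 1 when 1 was raised.

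The alternatives tried were quantile normalization again, subtraction of array medians, removal of the dimmest 25% or 50% of genes, trended and robust variance, array weights, averaging or separately testing the clusters of a gene, leaving out each array in turn, the replicate number as a block, the Xist level as a covariate, stricter thresholds, an unmoderated variance, and other list tests (an estimated correlation, fry, exact permutation and ranks). Leaving out control replicate 2 and DKO replicate 4 together was added after seeing the data. All 10 arrays entered every main comparison, and Stk3, clusters with several genes and unnamed clusters were left out of it.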

Results

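Pancreas RNA from 10 mouse samples was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, whose probes lie along the whole transcript and are summarised into transcript clusters. The samples fell into a control group (n = 5) and a group called DKO (n = 5). By its labels the DKO group lacked the hippo kinases MST1 and MST2. MST1 was lost through a null allele, which is not limited to the pancreas. MST2 was lost through a floxed allele, only where Cre recombinase acted under the Pdx1 promoter, which is active in pancreatic progenitors. Cells of the tissue in which Cre did not act would lack MST1 alone. Both kinases start the Hippo cascade, which restrains the transcriptional coactivators YAP and TAZ. After 1 cluster had been kept per gene, 19938 genes were compared. Array medians over all clusters lay between 7.12 and 7.15 on the log2 scale, and any pair of arrays correlated across genes with r between 0.976 and 0.995. Over the tested genes alone, array medians were 7.55 to 7.59 in control and 7.56 to 7.63 in DKO, where only DKO replicate 3 lay within the control range. The median log2 change over these genes was -0.006. The number of arrays, 5 per group, limits the precision, and the median standard error (SE) of a log2 change was 0.0754. The labels do not state that the arrays of a group came from different animals, so p-values measure the spread between these samples. They also give no sex, but Xist, the RNA of the inactive X chromosome, was high in 3 control and 2 DKO arrays, and the Y-linked genes Eif2s3y, Uty and Kdm5d were high in the other 2 control and 3 DKO arrays.

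The first comparison concerned the deleted genes. Stk4, which codes for MST1, measured 5.15 ± 0.09 (SD, n = 5) in control and 5.13 ± 0.06 (SD, n = 5) in DKO, a log2 change of -0.02 (limma adjusted p = 0.884). Its levels were 5.11, 5.23, 5.19, 5.01 and 5.20 in control replicates 1 to 5, and 5.10, 5.10, 5.21, 5.16 and 5.07 in DKO replicates 1 to 5. That level lay at the 14.2 percentile of all genes and within the range of sex-linked genes in arrays that do not express them, 3.99 to 5.75, so the cluster gave no check of the labels. Stk3, which codes for MST2, was not analysed here because no cluster was assigned to it alone.

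The main comparison asked which genes differed between DKO and control pancreas. Cym, the milk-clotting aspartic protease chymosin, rose most, from 8.44 ± 0.52 to 12.29 ± 0.13 (SD, n = 5 each), a 14.4-fold increase (log2 change 3.85 ± 0.21 SE, adjusted p = 1.18e-05). Kcnj15, an inwardly rectifying potassium channel, rose 11.96-fold (log2 change 3.58 ± 0.21 SE, adjusted p = 1.87e-05), and Pla1a, a phosphatidylserine-specific phospholipase, rose 6.47-fold (log2 change 2.69 ± 0.09 SE, adjusted p = 1.86e-07). Padi2, an enzyme that converts peptidyl arginine to citrulline, fell most, from 9.39 ± 0.51 to 8.01 ± 0.35 (SD, n = 5 each; log2 change -1.39 ± 0.24 SE, adjusted p = 0.0126). The Padi2 call ended when the variance was not moderated (adjusted p = 0.0585) and when control replicate 2 and DKO replicate 4 were both left out (0.0795), and held without any 1 array. In all, 487 genes passed an adjusted p of 0.05, of which 414 were higher and 73 lower in DKO.

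Among the other large increases were Clca3a1 and Clca3a2, a pair of closely related chloride channel regulators whose probes may not separate them (log2 changes 2.66 and 2.47). Tnnc1, the troponin C of heart and slow muscle, rose by 2.26, and Aadac, an esterase of the liver endoplasmic reticulum, by 2.12. The epithelial surface protein gene Plet1 rose by 1.91, Glipr1 by 1.90 and the pantetheinase gene Vnn1 by 1.90. The protease inhibitor gene Serpinb6b rose by 1.70 and the aldo-keto reductase gene Akr1cl by 1.63. The control levels of Akr1cl, 4.51 to 4.76, lay within the range of sex-linked genes in arrays that do not express them. Background may therefore compress its estimated change. Each of these increases had an adjusted p of 0.0147 or less. All were seen in 5 of 5 DKO arrays, which the rule for naming them required. Hepatocyte transcripts stood high in DKO replicate 1 (mean of 33 genes 8.74, against 6.001 to 6.46 in the other 9 arrays). Of the 33, 23 were listed before their values were looked at and the others because they were high in this array. The gap in the mean is thus partly a product of that choice. DKO replicate 1 also held the highest Aadac level, and without it Aadac was still higher by 1.73 (adjusted p = 0.00187). The Aadac call ended without moderated variance (adjusted p = 0.0667), and those of Aadac (0.0610) and Serpinb6b (0.0613) without control replicate 2 and DKO replicate 4 together.

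Decreases were smaller. Zp3, a glycoprotein of the egg coat, fell by 0.88 on the log2 scale (adjusted p = 0.00544), and Ptprn2, a protein of dense-core secretory vesicles, fell by 0.79 (adjusted p = 0.00971). The voltage-gated calcium channel gene Cacna1a fell by 0.63 (adjusted p = 0.00111), the store-operated calcium channel gene Orai2 by 0.56 (adjusted p = 0.00111) and the calcium-binding protein gene Cabp2 by 0.64 (adjusted p = 0.0164). Wfdc10 (-0.66), the transcription factor gene Ascl2 (-0.56) and the secreted protease gene Adamts1 (-0.52) also fell. The remaining 3 of the 12 were the small nucleolar RNA Snora33 (-0.89), the growth factor gene Egf (-0.54) and the potassium channel gene Kcnk16 (-0.54), whose adjusted p-values lay close to the threshold at 0.0482, 0.0445 and 0.0478. Egf and Snora33 each lost their call on leaving out any of 8 of the 10 arrays (highest adjusted p 0.104 and 0.123, both without control replicate 2), and Kcnk16 on leaving out any of 9 (highest 0.124, without control replicate 3). Cabp2 lost it without control replicate 3 (0.0521). With the replicate block the calls of Snora33 (0.120), Wfdc10 (0.0792) and Cabp2 (0.0605) ended. Leaving out control replicate 2 and DKO replicate 4 together also ended the calls of Zp3 (0.0523), Ptprn2 (0.0630), Wfdc10 (0.0817), Cabp2 (0.0979) and Adamts1 (0.0596). With fewer arrays in that fit, the changes of these genes were -0.88, -0.80, -0.62, -0.65 and -0.52, in that order, and thus similar in size. Without moderated variance the calls of Wfdc10 (0.0617) and Cabp2 (0.0614) ended.

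**Figure D1:**
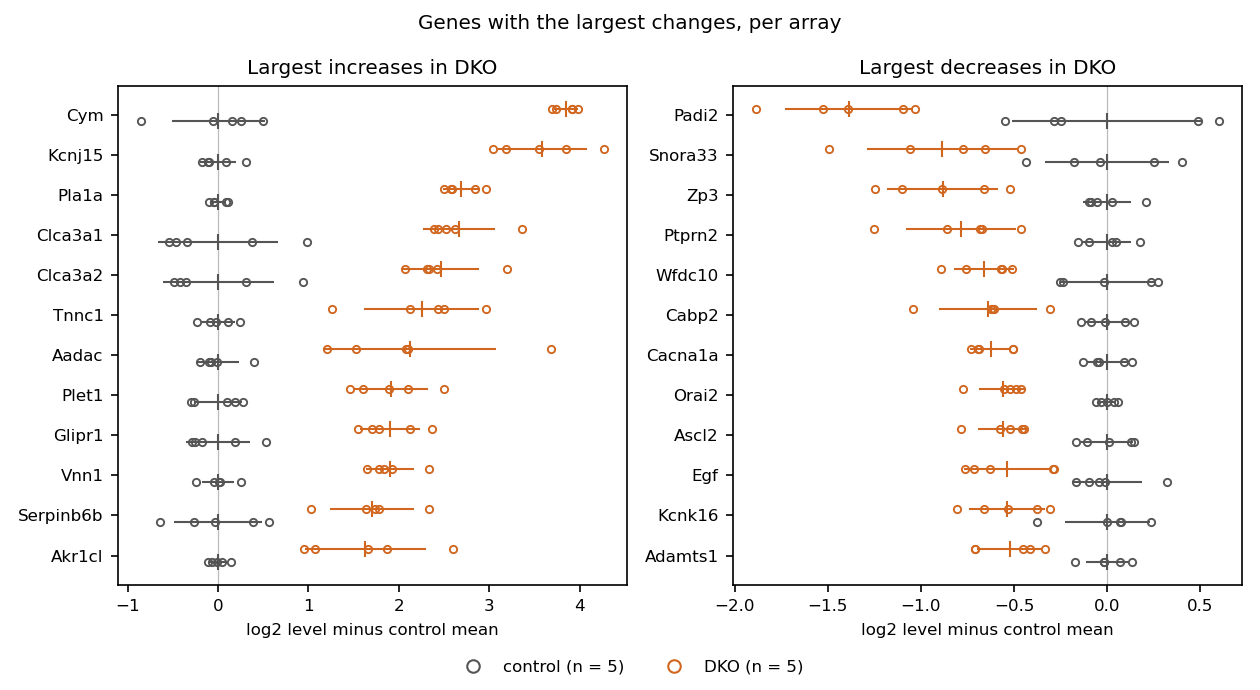
Log2 level of each array minus the control mean (horizontal axis) for the 12 named genes with the largest increases (left) and decreases (right) in DKO. Circles are arrays, vertical ticks are group means and horizontal bars are 1 SD (n = 5 per group). Cym in DKO lies 3.85 above control on average, whereas the largest decrease, Padi2, is -1.39.

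Of the higher genes 48 changed by a fold of 2 or more, and of the lower genes 1 did (Padi2). The median change was 0.45 among higher and -0.35 among lower genes. The groups did not overlap in 398 of the 414 higher and 71 of the 73 lower genes. Over all genes 4.80% had groups that did not overlap, against 0.794% by chance. At an unadjusted p of 0.05 there were 2958 genes, against 996.9 by chance. The share of higher genes among those called was 85.0% on the deposited values and 72.0% (321 higher, 125 lower) after quantile normalization again. It was 72.5% (271 higher, 103 lower) after subtraction of array medians, taken over the tested genes, which were mostly higher in DKO. Of the named genes past the test, quantile normalization ended the calls of Snora33, Tff2, Bgn, Mylk and Flna, and subtraction of medians those of Bgn, Lamb1, Mylk, Flna and Jun. Leaving out DKO replicate 1 gave 316 genes (276 higher, 40 lower), of which 299 were among the 487. The total also fell by more than 1.5 times without control replicate 2 (268 genes), control replicate 3 (260), DKO replicate 4 (324) or DKO replicate 5 (303). The count of lower genes fell by as much without control replicate 5 (43) or DKO replicate 2 (40) too.

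The next comparison concerned gene lists chosen before the data were examined, beginning with the pathway that was deleted. Target genes of YAP and TAZ rose as a list, with 9 of 23 measured members higher and none lower over all genes tested, and 15 higher adjusted over the list alone. Ankrd1, a nuclear ankyrin repeat protein, rose by 1.51 ± 0.16 (SE, log2 scale, adjusted p = 0.00104), and Ccn1, a secreted matricellular protein, by 1.43 ± 0.13 (adjusted p = 0.000336). Ajuba, a LIM protein that binds LATS kinases, rose by 0.73 and F3, the tissue factor of coagulation, by 0.66. Ccn2, the other matricellular target, was 0.72 ± 0.19 (SE) higher and did not pass (adjusted p = 0.0850). The mean of the list was 0.41 ± 0.04 (SE) higher in DKO, in 5 of 5 arrays. Its adjusted p was 2.24e-11 by camera with a preset correlation, 0.0234 with an estimated correlation and 0.0476 by exact permutation over all splits of the arrays, whose smallest unadjusted p is 0.00794.

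Genes of the Hippo pathway itself, without the deleted kinases, also rose as a list by camera (adjusted p = 7.43e-08) but not with an estimated correlation (adjusted p = 0.220). Of 22 members 5 were higher and none lower, and 11 were higher adjusted over the list alone. Amotl2 and Amot, angiomotin proteins that hold YAP at junctions, rose by 0.65 and 0.50. Wwc1, the scaffold KIBRA, rose by 0.48, and Lats2, a kinase that phosphorylates YAP, by 0.37. Without control replicate 2 and DKO replicate 4 together the calls of both ended (adjusted p = 0.0958 and 0.0772), and that of Wwc1 also without moderated variance and with the replicate block (0.0537 each). The fifth was Ptpn14 (0.33), named after its value was seen, which lost its call on leaving out any of 8 arrays (highest adjusted p 0.0827, without control replicate 2). Amotl2, Lats2 and Ptpn14 are members of the YAP target list too. Yap1 itself was 0.11 higher (adjusted p = 0.499) and Wwtr1, the gene of TAZ, 0.45 higher (adjusted p = 0.0540), and neither passed. The list mean was 0.20 ± 0.04 (SE) higher (adjusted p = 0.0476 by exact permutation).

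Genes of the pancreatic duct epithelium rose as a list, with 10 of 28 members higher and none lower. Adjusted over the list alone, 14 were higher and 1, Sox9, was lower. Cldn4, a tight junction claudin, rose by 1.37 ± 0.17 (SE, adjusted p = 0.00227), and Krt7, a keratin of simple ductal epithelia, by 1.22 ± 0.14 (adjusted p = 0.00112). Cp, the copper-carrying ferroxidase ceruloplasmin, rose by 1.05, and Clu, the secreted chaperone clusterin, by 0.69. Cp and Clu are also abundant in liver, and without DKO replicate 1, the array with high hepatocyte transcripts, they were still higher by 0.97 and 0.65 (adjusted p = 0.00197 and 0.00187). Sox9, a transcription factor of duct and progenitor cells, was 0.26 ± 0.08 (SE) lower (adjusted p = 0.149 over all genes), and Cftr, the chloride channel of duct cells, 0.50 ± 0.14 (SE) higher (adjusted p = 0.113). The list mean was 0.30 ± 0.04 (SE) higher, with an adjusted p of 2.26e-09 by camera, 0.00505 with an estimated correlation and 0.0476 by exact permutation. The duct and YAP target lists were the 2 of 30 lists past the threshold under both camera settings.

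Acinar cells make the digestive enzymes and form most of the exocrine pancreas. Of 25 measured acinar transcription factor and secretory genes 2 fell and none rose, while 6 were lower and 1 higher adjusted over the list alone. The 2 were Rbpjl (log2 change -0.45 ± 0.09 SE, adjusted p = 0.0225), a subunit of the acinar transcription complex PTF1, and Tmed6 (-0.34 ± 0.07 SE, adjusted p = 0.0359), a protein of the early secretory pathway. Rbpjl lies near Stk4, in the order of genes on the GRCm38.p6 assembly the 20th nearest of those measured, with Wfdc10 the 41st. Rbpjl lost its call without control replicate 3 (adjusted p = 0.0689), control replicate 5 or DKO replicate 4 and with the replicate block (0.0552), and Tmed6 without any of 7 of the 10 arrays (highest 0.0960, without control replicate 3). The list mean was lower by -0.18 ± 0.06 (SE) in 5 of 5 DKO arrays, with an adjusted p of 6.51e-05 by camera and 0.0476 by exact permutation, and adjusted p = 0.360 with an estimated correlation. Without DKO replicate 1, the array with high hepatocyte transcripts, the list was lower by -0.14 (camera adjusted p = 0.000242) and Rbpjl by -0.37 (adjusted p = 0.0134).

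None of the 21 measured digestive enzyme genes passed over all genes tested by limma (8 at an unadjusted p of 0.05), and 2 were lower adjusted over the list alone, the elastase Cela3a (-0.20) and the lipase-related Pnliprp2 (-0.36), of which the first belongs to a family of near-identical genes. The list mean was -0.21 ± 0.07 (SE) and its median -0.08. Much of the mean came from Ctrc, chymotrypsin C, which stood at 12.41 and 12.33 in control replicates 2 and 3 and between 7.50 and 8.60 in the other 8 arrays. The control mean level of the list was 12.52, near the top of the scale, where array maxima were 13.77 to 13.94. Falls of the brightest enzymes may be compressed there, which was not tested. Of 27 listed enzymes 21 were measured. The adjusted p of the list was 6.23e-05 by camera, 0.517 with an estimated correlation and 0.0794 by exact permutation. Islet endocrine genes had a mean of -0.20 ± 0.08 (SE), with 0 of 25 members past limma over all genes (7 at an unadjusted p of 0.05) and 2, Iapp (-0.32) and Nkx2-2 (-0.35), lower adjusted over the list alone. The islet list passed camera (adjusted p = 1.86e-06), but its adjusted p was 0.442 with an estimated correlation and 0.167 by exact permutation.

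**Figure D2:**
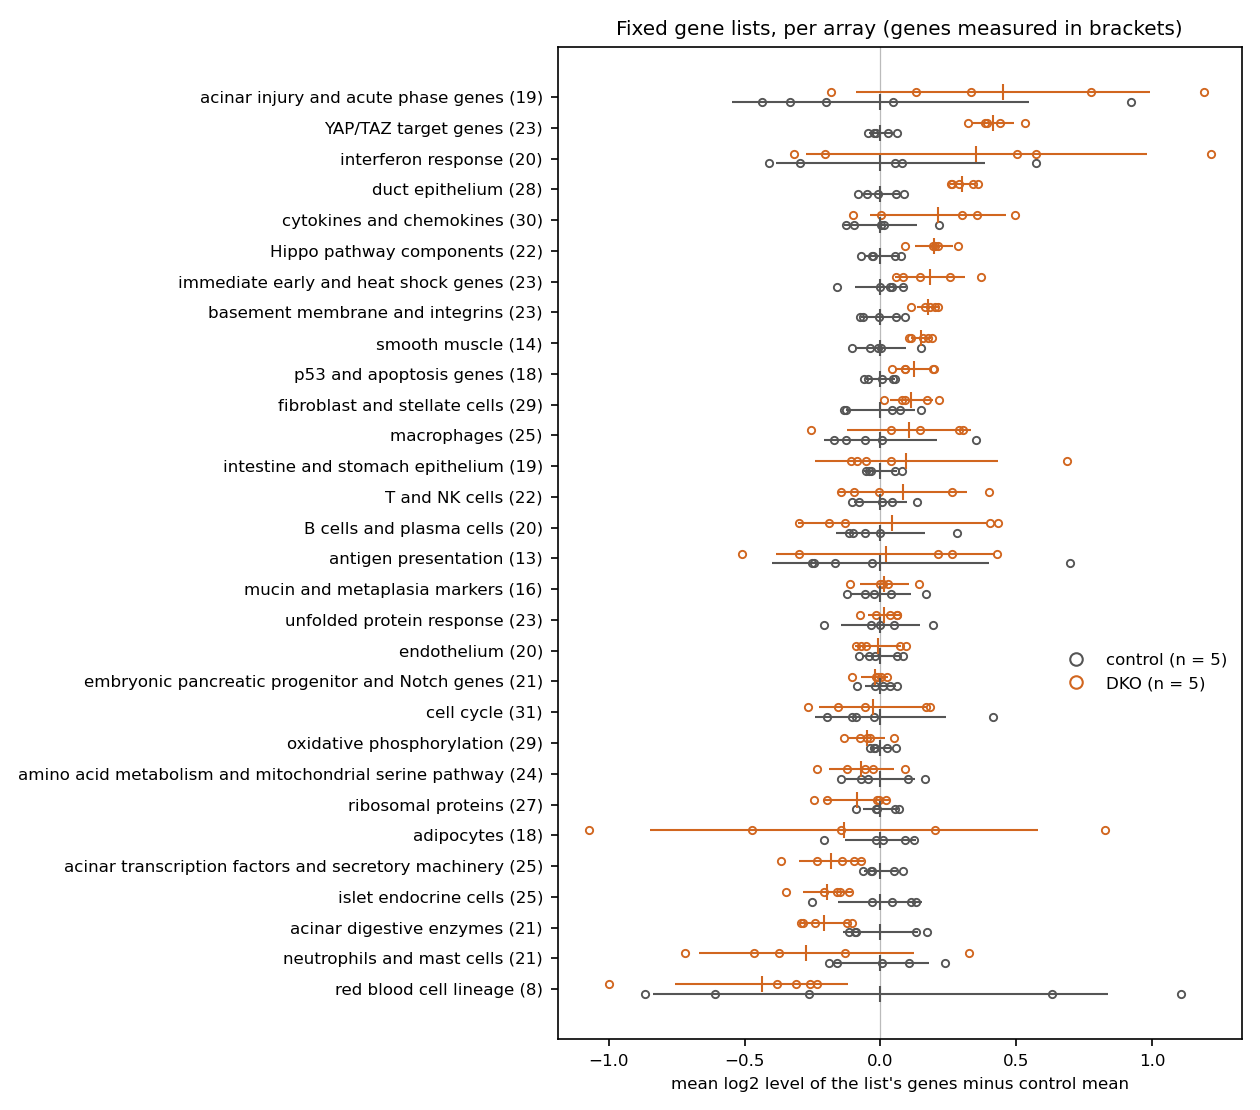
Mean log2 level of the measured genes of each fixed list minus its control mean (horizontal axis), per array, with the number of measured genes in brackets. Circles are arrays, vertical ticks are group means and horizontal bars are 1 SD (n = 5 per group). The YAP/TAZ target list lies 0.41 and the duct list 0.30 above control on average, with no overlap between the groups.

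Basement membrane and integrin genes rose as a list by camera (adjusted p = 0.000630) but not with an estimated correlation (0.442) or without the dimmest 50% of genes (0.0644). Of 23 members 4 were higher and none lower, and 6 were higher adjusted over the list alone. Itgb6, an epithelial integrin subunit that takes part in activating latent TGF-beta, rose by 1.24 ± 0.15 (SE, adjusted p = 0.00139), and the laminin chain gene Lama5 by 0.71, the latter not past the test without control replicate 2 and DKO replicate 4 together (adjusted p = 0.0630). Itga3 (0.48) and Lamb1 (0.40) each lost their call on leaving out any of 6 of the 10 arrays, with highest adjusted p-values of 0.0695 and 0.0742. The list mean was 0.18 ± 0.04 (SE) higher (adjusted p = 0.0476 by exact permutation). Among 29 fibroblast and stellate cell genes 1 rose, Bgn, a matrix proteoglycan (0.29, adjusted p = 0.0372), which lost its call on leaving out any of 8 arrays (highest 0.0996, without control replicate 2). Of 14 genes placed in the smooth muscle list 3 rose, the sarcomere protein gene Ldb3 (1.06), the myosin kinase gene Mylk (0.29) and the actin crosslinker gene Flna (0.39). The mean change of that list was 0.15 and its median 0.04. The calls of Mylk and Flna ended on leaving out any of 9 and 8 arrays (highest adjusted p 0.0963 and 0.0835). The Ldb3 call ended with the replicate block (0.0791) and without moderated variance (0.0519). In the fibroblast list 1 gene and in the smooth muscle list 3 genes were higher adjusted over the list alone. These lists had adjusted p-values of 0.0132 and 0.0259 by camera and of 0.645 and 0.558 with an estimated correlation. The fibroblast list lost its call without control replicate 3 or control replicate 4 (highest 0.212), and the smooth muscle list without control replicate 3, control replicate 4 or DKO replicate 2 (highest 0.128).

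Of 30 cytokine and chemokine genes 3 rose, the same count as adjusted over the list alone. Cxcl12, a chemokine that attracts CXCR4-bearing cells, rose by 1.45 ± 0.12 (SE, adjusted p = 0.000139), the membrane-bound chemokine gene Cxcl16 by 1.01 (adjusted p = 0.00137) and the growth factor gene Tgfb3 by 0.67 (adjusted p = 0.0171). Tgfb3 lost its call without control replicate 2 (0.0526) or DKO replicate 5. Its call also ended without moderated variance (0.0650) and without control replicate 2 and DKO replicate 4 together (0.111). As a list these genes passed camera (adjusted p = 0.0259), with adjusted p = 0.645 with an estimated correlation and 0.263 by camera without DKO replicate 2, where the mean change fell from 0.21 to 0.14. The camera call also ended without control replicate 1, control replicate 4 or DKO replicate 1 (0.0936).

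Of 19 acinar injury and acute phase genes 3 rose, Clu, the membrane-binding annexin gene Anxa3 (0.70) and the stress-induced chromatin protein gene Nupr1 (0.65). Nupr1 lost its call without control replicate 3 (0.0551), with the replicate block (0.0618) and without moderated variance (0.0661). Without control replicate 2 and DKO replicate 4 together the calls of Nupr1 (0.103) and Anxa3 (0.0528) ended. Adjusted over the list alone, 4 were higher. The mean of this list ranged from 8.90 to 10.26 within control and from 9.15 to 10.52 within DKO. It was 0.45 ± 0.34 (SE) higher in DKO (adjusted p = 0.00140 by camera, 0.429 by exact permutation), with adjusted p = 0.422 with an estimated correlation. Its difference was 0.26 without DKO replicate 4 (adjusted p = 0.0181 by camera) and 0.68 without control replicate 1. Of 23 immediate early and heat shock genes 3 rose, the stress-responsive transcription factor genes Atf3 (1.01 ± 0.13 SE, adjusted p = 0.00284), Klf6 (0.67) and Jun (0.43). Klf6 and Jun lost their calls on leaving out any of 5 and 8 arrays (highest 0.0733 and 0.0840), and 4 genes were higher adjusted over the list alone. Atf3 was also the only member past the test among 23 unfolded protein response genes, of which 2 were higher and 3 lower adjusted over the list alone. The immediate early list passed camera (adjusted p = 0.00779), with adjusted p = 0.558 with an estimated correlation, and lost its call without control replicate 4 (0.0810) or DKO replicate 4. None of 18 p53 and apoptosis genes passed by limma (4 at an unadjusted p of 0.05), 1 was higher adjusted over the list alone (Bid, 0.25), and the list was higher by camera (adjusted p = 0.0132), with adjusted p = 0.174 with an estimated correlation and 0.236 by camera without the dimmest 50% of genes.

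Immune, blood and housekeeping lists held few genes past the test. Of 20 interferon response genes 0 passed by limma (2 at an unadjusted p of 0.05), and 1 was higher adjusted over the list alone (Ddx58, an RNA sensor, 0.64). That list passed camera (adjusted p = 0.00344), with adjusted p = 0.645 with an estimated correlation and 0.161 by camera without DKO replicate 4, whose list mean of 8.54 was the highest of the 10. The mean change was 0.35, and 0.14 without that array. Neutrophil and mast cell genes (0 of 21 past limma, 4 at an unadjusted p of 0.05, mean change -0.27 ± 0.19 SE) passed camera at 0.0477 and red blood cell genes (0 of 8, 2 unadjusted, -0.44 ± 0.40 SE) at 0.0191, both with adjusted p = 0.645 with an estimated correlation. Adjusted over the list alone, 1 gene of the first was higher (Kit) and none of the second changed. Leaving out any of 5 arrays ended the call of the first (highest 0.290, without DKO replicate 3, where the mean change was -0.16) and leaving out any of 3 that of the second (highest 0.170, without control replicate 4, where it was also -0.16). Without DKO replicate 1 the neutrophil and mast cell mean change was -0.42 (adjusted p = 0.000565). Ribosomal protein genes (0 of 27 past limma, 0 at an unadjusted p of 0.05, mean change -0.09 ± 0.06 SE) and oxidative phosphorylation genes (0 of 29, 2 unadjusted, -0.05 ± 0.03 SE) had no member past the test over the list alone either. They passed camera at 0.000630 and 0.0271, again with adjusted p = 0.645 with an estimated correlation. Without DKO replicate 2 the ribosomal mean change was -0.048 (adjusted p = 0.0448 by camera). The oxidative phosphorylation list lost its call on leaving out any of 4 arrays (highest 0.190, without DKO replicate 2, where its mean change was -0.029).

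The remaining lists did not pass camera on all arrays. Among mucin and metaplasia markers the stomach-type mucin gene Muc6 (-0.39, adjusted p = 0.0210) and the trefoil factor gene Tff2 (-0.29, adjusted p = 0.0309) fell. Anxa10 rose by 1.44 (adjusted p = 0.0424), and by 1.22 to 1.66 with 1 array left out. Its control levels of 5.18 to 5.63 lay in the range of unexpressed genes. The list mean was 0.01 higher and the camera direction was down (adjusted p = 0.219). The counts were 2 higher and 2 lower adjusted over the list alone. Anxa10 lost its call on leaving out any of 8 arrays (highest 0.105, without control replicate 2), Muc6 without control replicate 5 (0.0579) and Tff2 without any of 7 arrays (highest 0.0911, without control replicate 2). Of 31 cell cycle genes 1 changed, the cyclin gene Ccnd1, which fell by 0.51 on the log2 scale (adjusted p = 0.0127, also past the test over the list alone, and 0.0512 with the replicate block), and the list had an adjusted p of 0.395. Of 22 T and NK cell genes 1 rose, the receptor gene Cd27 (0.49, adjusted p = 0.0356). Its control mean of 5.74 lay in the range of unexpressed genes. The Cd27 call ended on leaving out any of 7 arrays (highest 0.0859, without control replicate 5). Adjusted over the list alone, 1 was higher and 1, Cd6, lower, and the list had an adjusted p of 0.306. Adjusted p-values by camera were 0.0589 for macrophages, 0.766 for B cells and plasma cells, 0.766 for antigen presentation, 0.553 for endothelium and 0.395 for adipocytes, and no member of these lists passed over all genes by limma (6, 1, 0, 2 and 0 members at an unadjusted p of 0.05, in that order). Adjusted over the list alone, 1 macrophage gene was lower (C1qa) and no gene of the other 4 changed. For embryonic pancreatic progenitor and Notch genes the value was 0.642 (mean -0.02, median 0.01), and for the unfolded protein response 0.428 (mean 0.01, median and camera direction down). It was 0.238 for intestine and stomach epithelium (mean 0.10, or -0.05 without DKO replicate 1, median and camera direction down) and 0.0672 for amino acid metabolism (mean -0.07). The amino acid list passed on leaving out any of 5 arrays (lowest 0.00858, without control replicate 2), among them DKO replicate 1 (mean -0.11, adjusted p = 0.0437), and its mean was -0.03 without DKO replicate 2 (adjusted p = 0.263). Leaving out 1 array also brought past camera the lists of macrophages (3 arrays, lowest 0.000138), cell cycle (2 arrays, 0.0230), antigen presentation (0.0175), the unfolded protein response (0.0335), adipocytes (0.00105) and T and NK cells (0.0230), the last 4 without 1 array each. The progenitor, intestine and amino acid lists had 0 members past limma over all genes or over the list alone, and 3, 0 and 8 at an unadjusted p of 0.05.

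By camera with its preset correlation 18 of 30 lists passed, 11 up and 7 down. The same test called a median of 12 lists over 99 other groupings of the 10 arrays. With an estimated correlation 2 passed, by fry, which tests whether the genes of a list move on balance in 1 direction, 8 passed, and by exact permutation of the list mean 5 passed. Those 5 were the YAP target, duct, Hippo component, basement membrane and acinar transcription factor lists. Each had the smallest p that the splits allow (0.00794), and their common adjusted p of 0.0476 rests on all 5 being tied there. With fewer lists at that p none would have passed, so the 5 passes are not separate support. Quantile normalization again ended the camera calls of the neutrophil, smooth muscle and ribosomal lists, and subtraction of array medians those of the neutrophil and red blood cell lists.

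The last comparison concerned the spread within each group. The median SD over genes was 0.109 in control and 0.125 in DKO, a ratio of 1.14, and the mean absolute deviation per array did not differ between the groups (exact two-sided permutation p = 0.310). No list differed in spread after adjustment (exact permutation, 0 of 30 lists at an adjusted p of 0.05, 1 at an unadjusted p of 0.05). The first principal component held 27.5% of the variance and separated DKO replicate 1 (43.6) from the other 9 arrays (-12.2 to 0.86). Hepatocyte genes were high in the same array. Alb, the gene of serum albumin, measured 13.4 there against a median of 9.25 in the other 9 arrays, and Afp, the gene of alpha-fetoprotein, 11.3 against 5.88.

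**Figure D3:**
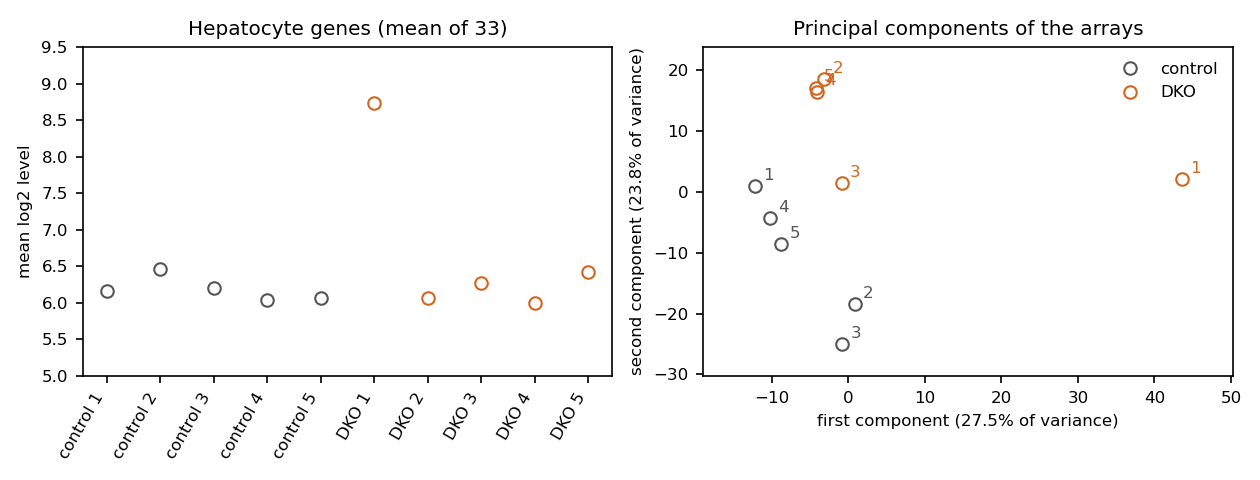
Left, mean log2 level of 33 hepatocyte genes in each array, with 8.74 in DKO replicate 1 and 6.001 to 6.46 in the other 9 arrays (the axis does not start at 0). Right, position of each array (labelled by replicate number) on the first and second principal components, in component units, with 27.5% and 23.8% of the variance. DKO replicate 1 lies at 43.6 on the first component. On the left, 23 of the 33 genes were listed before their values were looked at, and the others because they were high in DKO replicate 1.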

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

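Tests of the duct pattern, the count of lower genes near Stk4 and the acinar list without Rbpjl were chosen after the results were seen. Those of the liver transcripts, of other genes near Stk4 and of other groupings of the arrays were chosen before they were run. The liver tests nonetheless followed hepatocyte genes already seen high in DKO replicate 1. A single array stood apart from the other 4 of its group in 18 of 300 groups of 5 examined, by Dixon's gap ratio (gap to the nearest array over the whole range), where chance alone gives about 15. The array concerned was DKO replicate 1 in 6 of the 18.

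DKO replicate 1 stood apart on the first principal component (gap ratio 0.929, value 43.6 against -4.25 to -0.87 in the other DKO arrays) and in the intestine and stomach list (0.816, list mean 6.83 against 6.04 to 6.18), which includes Apoa1 and Fabp1, genes that liver also expresses. Its 4 low values were Rnase1 (0.901, level 12.81 against 13.13 to 13.17), Zg16 (0.818, 12.55 against 12.88 to 12.95), Nkx2-2 (0.866, 8.42 against 8.78 to 8.84) and Sox9 (0.826, 10.16 against 10.51 to 10.59). In this array 117 genes lay over 2 above the median of the other arrays, against 3 to 27 in the others, led by plasma protein genes such as Serpina1c (10.9 against a median of 4.53) and Ahsg (13.0 against 7.08). Of the 33 hepatocyte genes, 23 were listed before their values were looked at and the others because they were high in this array. Of the 33, 6 lie above the median level of all genes in the other arrays too, and 1 is in a fixed list. If liver tissue or cells were in the sample, other abundant hepatocyte genes should be high too, and 16 of 23 hepatocyte genes whose values had not been looked at lay over 1 above the median of the other 9 arrays, among them Trf (12.9 against 10.3) and Apoc1 (10.9 against 7.91). Others of the 23 were flat, such as Mup3 (3.76 against 3.73), Cyp2c29 (4.28 against 4.23), Hamp (4.26 against 4.23) and Hsd17b13 (10.37 against 10.50). A rise of hepatocyte genes common to the DKO animals is argued against. The mean of the hepatocyte genes in the other 4 DKO arrays differed from control by 0.00192 ± 0.12 (SE). Liver RNA in this sample may therefore account for its distance from the others, while a change within this pancreas alone stays open and untested.

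The duct list was higher in DKO (10 of 28 genes past the test), and the means of the acinar factor and enzyme lists were lower, with 2 of 25 and 0 of 21 genes past it. With an estimated correlation the acinar lists did not pass (adjusted p = 0.360 and 0.517). The duct mean rose relative to the islet mean by 0.498 ± 0.11 (SE, exact permutation p = 0.00794, the smallest the design allows). Relative to endothelium it rose by 0.312. These differences follow from list means already seen, so the p-value is descriptive and adds no support of its own. The duct, islet and endothelium lists thus did not rise alike. A lower acinar share that raises all other cell types alike is argued against to that extent. The duct genes were split loosely by function after their values were seen. The 14 transcription factor, transport and cilium genes (the scaffold Wwc1 included) differed by 0.0913 ± 0.05 (SE, exact permutation p = 0.111). Of these 14, 2 were higher, Wwc1 and Pkhd1. The 14 keratin, junction and surface genes (the secreted Clu and Cp included) differed by 0.51 ± 0.04 (SE, 8 of 14 higher). The sets differed by 0.42 (exact permutation p = 0.00794). A split made on seen values decides nothing. More duct cells that bring their whole profile stay open, as do genes of the second set induced within duct cells or in other cells.

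Of the 100 measured genes nearest to Stk4, 3 were lower in DKO (Rbpjl, Wfdc10 and Slc35c2, the last not past the test without control replicate 2), where 0.366 were expected (one-sided exact hypergeometric p = 0.00592, on genes that had drawn attention), and 0.929% of 19908 such windows held as many. Counted either way the window held 3 changed genes, against 2.44 expected, and the 100 nearest to Stk3 held 2, with 0 lower. Strain variants carried along with the targeted Stk4 allele may contribute, since the background is mixed. Among the other genes of that window 12 had an unadjusted p under 0.05, equal to the median of all windows (12, SD 4.003), so this test gave no sign of such variants and, as they need not touch many genes, does not exclude them. The mean of the acinar transcription factor and secretory list without Rbpjl was lower by -0.170 (unadjusted exact permutation p = 0.00794). Of its genes Tmed6 alone passed the test, which it failed on leaving out any 1 of 7 arrays, and the full list did not pass with an estimated correlation (adjusted p = 0.360), so a fall of Rbpjl with its acinar partners and linked variants both stay open.

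Among controls, Lama5 was low in control replicate 4 (gap ratio 0.748, 8.34 against 8.75 to 8.89), and Rrm2 was high there (0.721, 10.04 against 9.19 to 9.43). The same array was high in the cell cycle list (0.714, mean 9.64 against 9.03 to 9.20) and in the B cell and plasma cell list (0.714, mean 6.82 against 6.42 to 6.54). Control replicate 2 was high in Bst2 (0.778, 8.59 against 8.14 to 8.24) and in the antigen presentation list (0.766, mean 9.18 against 8.24 to 8.46). In the DKO group, Clca3a1 was high in replicate 4 (0.765, 10.10 against 9.13 to 9.36) and Anxa3 in replicate 2 (0.719, 9.98 against 9.61 to 9.71). DKO replicate 5 was low in Muc6 (0.819, 5.87 against 6.07 to 6.11) and Cdx2 (0.782, 5.93 against 6.14 to 6.20) and high in Ndufa9 (0.744, 10.06 against 9.78 to 9.85). The red blood cell list was low in DKO replicate 3 (0.807, mean 7.098 against 7.71 to 7.86).

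Chance in the grouping of the 10 arrays is argued against as the source of the gene counts. Of 100 groupings into 5 and 5, drawn from 126, the real one alone (1 of 100) reached 487 genes, 414 higher and 73 lower. The highest of the others were 4, 3 and 3. A share of 1 in 100 is the lowest such a draw can give. Chance is not excluded for the number of lists past camera with its preset correlation, since 9 of the 100 groupings gave as many as the real 18, and the highest of the others gave 23.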

How the results depend on the processing

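The setting without control replicate 2 and DKO replicate 4 was chosen after seeing the data, and the pseudocount setting was not run because the values are log2 levels. Of 118 named genes, 58 passed the test, of which 40 passed it without any 1 array, and none reversed. Of the 58, 27 kept their call under every setting in which they were tested. Named genes were not tested at the stricter thresholds, and a gene removed as dim was not counted as lost. Without the dimmest 50% of genes, 96 of the 118 remained in the fit. The call ended for 23 of the 58 without moderated variance, 28 without control replicate 2 and DKO replicate 4 together, 19 with the replicate block and 6 with the Xist level as a covariate. The replicate block left the estimated changes as they were and used up degrees of freedom, and the fit without those 2 arrays held fewer arrays. A call that ended there need not mean a smaller change. Stk4 stayed short of the threshold and the spread did not differ between groups under any setting that gave a value. Lower genes numbered 125 after quantile normalization again and 46 with the Xist level as a covariate, and higher genes 271 after subtraction of array medians. Total, higher and lower genes numbered 163, 154 and 9 at an adjusted p of 0.01, and 138, 131 and 7 with a fold of 1.5, where the stricter threshold itself lowers them. They were 298, 264 and 34 without moderated variance, and 151, 146 and 5 without control replicate 2 and DKO replicate 4, where 149 of the 151 were among the 487. With each array left out in turn, the total ranged from 260 (without control replicate 3) to 433 (without DKO replicate 3), higher genes from 232 to 372, lower genes from 28 to 64 and lists past camera from 12 (without control replicate 4) to 21, with fewer arrays in each fit. Lists past the test numbered 2 with an estimated correlation, 8 by fry and 5 by exact permutation, and 12 of 26 lists were past camera without the dimmest 50% of genes. The numbers in the titles did not pair the arrays (r of same-numbered deviations -0.27 to 0.29, 2 of 5 pairs above 0.1, 0 control arrays closest to their own number). The replicate block gave 178 genes (162 higher, 16 lower), 169 of them among the 487, and 19 lists. Apart from the thresholds and the left-out arrays, the cause was not tested. Dim genes such as Stk4 lie too close to background for a fall to be measured.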

Other observations

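The values below were picked out after the data were seen, and no test was made of them.

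Several secreted and immune genes varied strongly between arrays of the same group. The regenerating islet-derived genes, small secreted lectins made by stressed acinar cells, were high in control replicate 1 and DKO replicates 2 and 4. Reg3b measured 13.4, 12.3 and 13.3 in these arrays, 11.1 in DKO replicate 1, and 6.15 to 8.95 in the other 6, and Reg3g measured 12.4, 10.4 and 12.4 against 6.26 to 7.69 in the other 7. Reg2 measured 13.3, 12.2 and 13.3 in these 3 arrays and 8.998 to 10.3 in the other 7.

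Gbp4, Iigp1 and Cxcl10, which interferon induces, were high in control replicate 2 and DKO replicate 4, while the mean of the fixed interferon list was as high in DKO replicates 1 and 2 (7.89 and 7.82) as in control replicate 2 (7.89). Gbp4, a guanylate-binding protein, measured 9.87 and 9.60 there and 6.001 to 7.69 in the other 8 arrays. Iigp1, an immunity-related GTPase, measured 10.3 and 9.95 against 6.14 to 7.82, and the chemokine gene Cxcl10 9.84 and 9.51 against 6.78 to 8.01. Fat cell genes also varied within DKO. Adipoq, the gene of adiponectin, measured 9.41 in DKO replicate 2, 5.77 in DKO replicate 3 and 6.46 in DKO replicate 1, against 7.56 to 8.34 in the 5 controls, and Retn, the gene of resistin, measured 10.4, 6.68 and 7.096 in these DKO arrays against 8.49 to 9.39 in the controls.

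Outside the named genes, 0 of 1621 clusters with several gene symbols passed limma's adjusted threshold (79 at an unadjusted p of 0.05), and 6 of 12146 clusters with no gene name here did (1277 at an unadjusted p of 0.05).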
